A study of Mus musculus with 19 samples.

How the data were processed

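5hmC was measured in genomic DNA of 15 pre-iPSC libraries (WT and KO at days 0, 2 and 10) and 3 mESC libraries. An input library, with no treatment in its label and no list of its own, completed the 19 samples. Per the labels' protocols, DNA was sonicated to 200 to 500 bp. 5hmC was labelled with an azide-modified glucose by T4 beta-glucosyltransferase, coupled to biotin, captured on streptavidin beads and amplified over 14 cycles. The medium held ascorbic acid at 50 µg/mL with 2i and was renewed every 2 days, and cultures were split on day 4, per the labels. The labels give the same treatment to every library except the input, day 0 included. Samples were grouped by their titles. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

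Per the submitters' processing notes, the authors used Bowtie, SAMtools and MACS2 and the mm9 build; versions are not given in the sources used here. Peaks were called per library, as each of the 18 samples has its own deposited list. Each list holds 10 columns, with the authors' score (the whole part of 10 times -log10 p, apart from 1 peak), the fold enrichment as a linear ratio at the summit, and -log10 of p and of q, per the MACS2 column layout of the deposited files. The deposited run names carry a p threshold of 0.0001. A label says that peak calling was not performed for the mESC samples, yet their lists have the same layout and thresholds, and they were used as deposited. The build is taken from those notes. The gene table at hand is of GRCm38, and on 10 chromosomes peaks lie past its last gene, so it was not used for names or positions. Scores, folds and -log10 p are the authors' own values per peak and served only to rank or filter peaks within a list.

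Relative depth was recovered from the deposited fold values, which step by what 1 read is worth. In 14 of the 15 pre-iPSC lists the background per bp was 0.0155 and matched the shared input; WT D0 C had its own background. Depths relative to the input were 1.40, 1.47 and 0.968 (WT D0 A, B and C), 1.61, 1.35 and 1.24 (D2), 1.37, 1.64 and 1.03 (D10), 1.23 and 1.15 (KO1 and KO2 at D0), 1.67 and 1.23 (D2), and 1.47 and 1.16 (D10). Absolute depth is unknown. The 149 peaks on chromosome Y or the mitochondrial genome were left out of comparisons.

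Lists were compared on chromosomes 1 to 19 and X. To give lists a single length, the 55130 strongest peaks of each pre-iPSC library by the authors' -log10 p were used (the shortest list's number), and mESC lists were used whole. Peaks were called shared at 1 bp of overlap. Peak number (log2) and shares were tested by two-sided exact permutation, as was KO against WT at each day; for overlap with the WT lists of the same day, the overlaps were recomputed for each assignment. A permutation F over the 3 days has 0.00357 as its smallest p. Regions are the merged peaks of the 9 WT libraries. Shares of regions have 95% Wilson intervals.

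Windows of 10 kb were tested on log2(covered bp + 200), where covered bp lie under the strongest peaks and each library is scaled to the mean total. Windows with a mean of at least 500 covered bp entered limma (lmFit, eBayes with trend and robust), with Benjamini-Hochberg adjustment at 0.05 within each contrast. Log2 changes are on this scale and understate changes of sparsely covered windows. The 9 WT libraries made a fit of their own; KO contrasts and interactions came from a fit of all 15 in 6 groups. The planned test was on genes, with gene lists, promoter regions and the distribution of peaks over genes; these needed an mm9 annotation and were not run, and windows took their place, as laid down beforehand. Windows named are the 5 with the largest rise and the 5 with the largest fall per contrast, past the threshold and with groups that do not overlap; regions named are the 5 longest gained and lost. Of the windows that differ between KO and WT at D0 and D2, the largest is given. In simulated data on 14776 windows for D10 against D0, limma recovered 0%, 39% and 79% of 200 windows changed by log2 1, 2 and 3, with 0, 0 and 5 false calls. With so few windows changed, the adjusted threshold was stricter than in the real contrast, so these shares do not give its power.

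KO1 and KO2 were taken from the titles as the same lines on each day, so the line was taken to pair KO samples. The deviations of a line from its group means correlated between days by 0.23 to 0.34 over windows. These windows include chromosome 5, where KO1 was in excess on each day, and no correlation without it was computed. Run names come in styles that may mark batches: WT A in the first, WT B with KO1 in the second, WT C with KO2 in the third.

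The groups, the rule for named items, most alternatives and the main tests of peak number, gained and lost regions, the share with the 2-of-3 mESC set, windows between WT days and between KO and WT, interactions and the mESC time course were fixed before the data were examined. Alternatives were a stricter q, all deposited peaks with and without scaling, covered length, a larger overlap (50%), pseudocounts of 50 and 1000 bp, other minimum coverage, a fit of WT days on all 15 libraries, a replicate block and leaving out each library. Chosen after the data were seen were the contrasts within KO, the shares with the 12 and 72 hour mESC lists, the overlap of pre-iPSC lists, the classes of regions by day, the unpaired test of the change in peak number, windows of 5 and 20 kb, median-centring, the run-name style as a block, leaving out chromosome 5 or 8, mESC lists of a single length, held-out regions and windows, tests by chromosome, the KO line alone as a block, leaving out KO libraries within KO, and a count of weaker deposited peaks in named windows. The larger overlap cannot change which regions have a peak, because each peak lies inside its merged region; for regions it tests nothing. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and data.table (version 1.17.8).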

Results

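5-Hydroxymethylcytosine (5hmC), the base that TET enzymes make by oxidising 5-methylcytosine, was mapped by enrichment sequencing in mouse pre-iPSCs. These cells are stalled intermediates of fibroblast reprogramming, derived from mouse embryonic fibroblasts. They were cultured with ascorbic acid and 2i, a pair of inhibitors (CHIR-99021 against GSK3 and PD-0325901 against MEK), and harvested at days 0, 2 and 10 (D0, D2 and D10). Wild-type cells (WT) had 3 libraries per day, replicates A, B and C. Knockout cells (KO) had 1 library per day of KO1 and of KO2, taken here as a pair of lines of the same arm. The labels name neither the deleted gene nor whether both lines lack the same gene. V6.5 mouse embryonic stem cells (mESC) had 1 library each at 0, 12 and 72 hours, and so no replicates. Each library came with a list of the authors' MACS2 peaks, and the 18 lists held 1601520 peaks in all. Coordinates below are on mm9, and no gene annotation of that build was used here, so regions are given by position alone. Depth was read from the steps of the peaks' fold values, relative to the shared input library. It ranged from 0.968 to 1.64 times the input in the 9 WT libraries and from 1.15 to 1.67 times in the 6 KO libraries. It could not be read for the mESC libraries.

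The number of 5hmC peaks over the 10 days of conversion was compared first. WT libraries held 90113 ± 26933 peaks at D0, 133095 ± 27467 at D2 and 73043 ± 16140 at D10 (SD, n = 3 each). They covered 38.8 ± 17.3 Mb, 55.2 ± 10.7 Mb and 25.9 ± 7.39 Mb of the genome (SD, n = 3 each). The spread between replicates was wide: D0 libraries alone ran from 61975 peaks (C) to 115652 (B). A difference in log2 peak number between the 3 days did not pass a two-sided exact permutation test (p = 0.0857). The replicate that held the fewest D0 peaks decided this call, since p was 0.0286 without WT D0 C. WT letters go with styles of the run names, which may mark batches, and C held the fewest peaks on each day. Replicate C also had the lowest WT depth on each day (0.968, 1.24 and 1.03 times the input), and WT D0 C had its own background rather than the shared input. These differences were not told apart. Within A, B and C, log2 peak number differed by 0.80, 0.19 and 0.78 (D2 minus D0) and by -0.90, -0.77 and -0.94 (D10 minus D2). With the letters as blocks the exact permutation p was 0.0278, the smallest that this test can give. Between pairs of days, log2 peak number differed by 0.59 (D2 minus D0, exact p = 0.2), -0.87 (D10 minus D2, exact p = 0.1) and -0.28 (D10 minus D0, exact p = 0.4). With 3 libraries against 3 the smallest p is 0.1.

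KO libraries held 61125 and 86943 peaks at D0, 138474 and 114143 at D2, and 112303 and 111281 at D10 (KO1 and KO2). The KO minus WT difference in log2 peak number over the 3 days was 0.11 (two-sided exact permutation within days, 1000 assignments, p = 0.598). By day it was -0.26 at D0 (exact p = 0.4), -0.06 at D2 (exact p = 0.9) and 0.64 at D10 (exact p = 0.2), where 2 libraries against 3 allow no p below 0.1. At D10 both KO libraries lay above all 3 WT libraries, which held 55134 to 86465 peaks.

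**Figure D1:**
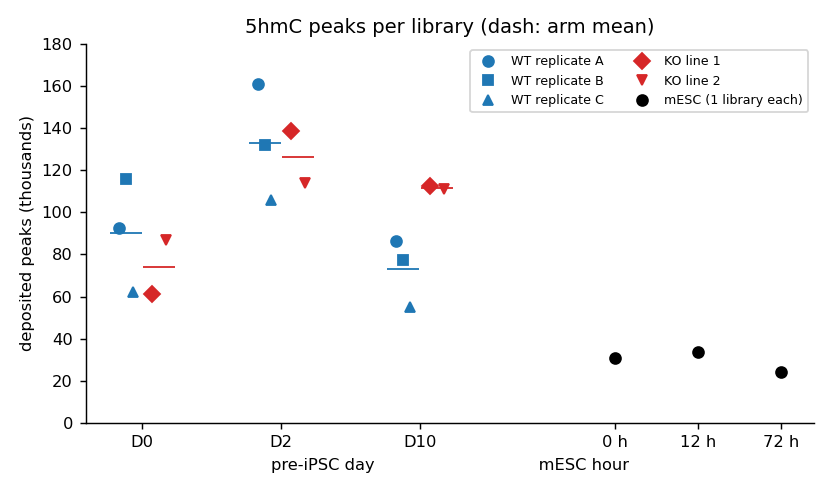
Deposited 5hmC peaks per library (axis in units of 1000 peaks) by day of conversion (pre-iPSCs) or hour (mESC). Each point is a library and each dash the mean of its arm; WT D10 libraries held 55134 to 86465 peaks, and the KO D10 libraries 111281 and 112303.

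The positions of the peaks differed more between days than between replicates. Peak lists were compared by the bp they shared as a percentage of the bp in either, with each list restricted to its 55130 strongest peaks by the authors' -log10 p. Lists of WT D0 and D2 overlapped by 18.3% on average (9 pairs, 16.9 to 19.3%). Lists of WT D2 and D10 overlapped by 10.9% (8.34 to 13.6%), and those of D0 and D10 by 4.24% (3.14 to 5.32%). Every pair from the same day overlapped more than every pair from different days: 26.2 to 50.7% at D0, 45.5 to 48.6% at D2 and 27.6 to 34.8% at D10 (3 pairs each).

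The regions behind this turnover were found by merging the peaks of the 9 WT libraries into 296639 regions. A region was called gained when all 3 libraries of the later day and none of the earlier day had a peak in it, and lost the other way round. From D0 to D2, 24995 regions (14.1 Mb) were gained and 7579 (4.06 Mb) lost. From D2 to D10, 9957 regions (5.29 Mb) were gained and 41265 (28.0 Mb) lost. Across the whole course from D0 to D10, 19240 regions were gained and 26417 lost, and only 3617 had a peak in all 6 libraries of both days. Presence in 3 libraries against 3 gives no p per region, and the counts depended on the lists used. With the strongest peaks alone, which gives each library the same number, 9005 regions were gained and 8725 lost from D0 to D2, 11144 and 15306 from D2 to D10, and 15151 and 17494 from D0 to D10. Without WT D2 C, 42414 regions were gained from D0 to D2, and without WT D0 C, 25400 were lost. Without WT D10 C, 18870 regions were gained from D2 to D10 and 34023 from D0 to D10. Without WT D0 C, 56361 were lost from D0 to D10.

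The longest regions gained from D0 to D2 lay on chromosome 2 (179923847 to 179929889, 6043 bp), chromosome 18 (73848860 to 73853469, 4610 bp), chromosome 8 (91553133 to 91557196 and 46035627 to 46039317) and chromosome 15 (75932829 to 75936548). The chromosome 2, 8 and 15 regions kept a peak in all 3 WT libraries at D10. The chromosome 18 region was transient: all 3 WT libraries had a peak at D2 and none at D0 or D10. The longest region lost by D2 was on chromosome 11 (16795237 to 16797380, 2144 bp), and those next in length were on chromosome 3 (131470390 to 131472463 and 95456398 to 95458380), chromosome 6 (85915290 to 85917147) and chromosome 8 (29854349 to 29856155). None of these 5 had a peak in any mESC list.

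The longest regions gained from D2 to D10 lay on chromosome 6 (142345231 to 142348950, 3720 bp), chromosome 2 (76547241 to 76550888, 3648 bp), chromosome 1 (189176873 to 189179737), chromosome 10 (69452160 to 69454752) and chromosome 5 (68610870 to 68613200). All 5 had a peak in the 12 hour and 72 hour mESC lists. KO1 had a D10 peak in none of them, and KO2 in those of chromosomes 6 and 1. The longest lost from D2 to D10 were on chromosome 13 (53328768 to 53333699, 4932 bp), chromosome 18 (the transient region above), chromosome 8 (127544240 to 127548569), chromosome 12 (12943239 to 12947137) and chromosome 2 (147013155 to 147017025). Both KO libraries of D10 had a peak in all 5, and the 72 hour mESC list in none. Over D0 to D10 the same rule added a gained region on chromosome 17 (84858427 to 84863582, 5156 bp) and a lost region on chromosome 9 (72658311 to 72662137, 3827 bp).

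A test with replicate error was made on 14776 windows of 10 kb, by the bp under the strongest peaks, with limma and Benjamini-Hochberg adjustment at 0.05. From D0 to D2, 2189 windows rose and 440 fell; from D2 to D10, 2040 rose and 4911 fell; from D0 to D10, 3356 rose and 4000 fell. The median window shifted by 0.38, -0.60 and -0.18 (log2) in these contrasts. Relative to the median window the splits were more even, with 1252 up and 824 down, 2986 up and 3482 down, and 3694 up and 3725 down. With all deposited peaks and no scaling they were 4673 up and 132 down, 829 up and 14213 down, and 3031 up and 8712 down. With every window that had a covered bp tested, the balance of D0 to D2 turned to 3643 up and 5624 down; the other contrasts gave 8176 up and 8203 down, and 9953 up and 12134 down. In a fit of all 15 libraries the D2 to D10 split was 1094 up and 5201 down. In windows with a mean of at least 2000 covered bp, D0 to D10 turned to 113 up and 38 down. The D0 to D2 count was 1440 without WT D2 A, 1521 without WT D2 B, 1620 without WT D2 C and 1748 without WT D0 A. Its falls numbered 147, 122 and 722 without WT D0 A, B and C. Rises from D2 to D10 numbered 1239 and 1282 without WT D10 B and C, and the D0 to D10 balance turned to 3240 up and 2728 down without WT D0 A and to 3174 up and 2620 down without WT D0 B.

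Covered bp are those under the 55130 strongest peaks, so a window with none can still hold weaker deposited peaks. Among windows past the threshold whose groups did not overlap (10% of windows would do so by chance), the largest rise from D0 to D2 was at chromosome 3, 96970001 to 96980000. It held 3150 ± 155 covered bp at D2 and no covered bp at D0 (SD, n = 3, limma adjusted p = 0.000255), where 2 of the 3 whole lists had a weaker peak. Close behind was chromosome 8, 126130001 to 126140000, with 4255 ± 292 bp at D2 against 93.4 ± 162 at D0 (log2 change 4.05, SE 0.46, limma adjusted p = 0.000936). Under all deposited peaks this window held 1891, 4518 and 0 bp at D0 (A, B and C) and 5858, 5020 and 4503 bp at D2. In B the rise thus came mostly from the cut to the strongest peaks. Windows starting at 31980001 on chromosome 17, 134120001 on chromosome 6 and 79430001 on chromosome 10 followed, with log2 changes of 3.95, 3.93 and 3.92. In each of these, 2 of the 3 whole D0 lists had a deposited peak. The largest falls to D2 went to no covered bp, from 2041 ± 680 bp on chromosome 13 (60550001), 1841 ± 132 on chromosome 18 (69820001), 1991 ± 1166 on chromosome 6 (121090001), 1778 ± 593 on chromosome 8 (74830001) and 1887 ± 927 on chromosome 5 (106100001). Their limma adjusted p ran from 0.000255 to 0.00646. In all 5, each D2 library had a weaker deposited peak.

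From D2 to D10 the largest rise was at chromosome 15, 77590001 to 77600000, with 5445 ± 853 bp at D10 and no covered bp at D2 (SD, n = 3, limma adjusted p = 8e-06). Windows on chromosome 1 (189170001), chromosome 12 (111850001) and chromosome 17 (84860001) also had none at D2, and reached 4635 ± 643, 4623 ± 533 and 4424 ± 445 bp. The window at 115180001 on chromosome 5 reached 5580 ± 769 bp from 36.3 ± 62.9 (log2 change 4.64, SE 0.40, limma adjusted p = 3.42e-05). Under all deposited peaks it held 2376, 899 and 1020 bp at D2 (A, B and C) and 4823, 5411 and 3812 bp at D10. In each of the 5 rises, 2 or 3 of the whole D2 lists had a deposited peak. WT D2 lists were the longest on average and so lost most to the cut. The largest falls, all to no covered bp at D10, were from 4517 ± 243 bp on chromosome 13 (53280001), 3886 ± 110 and 3761 ± 579 on chromosome 11 (76160001 and 76170001), 3899 ± 539 on chromosome 17 (29200001) and 3822 ± 275 on chromosome 12 (78010001). In 4 of these 5 no D10 library had any deposited peak; at 76170001 on chromosome 11, 2 had a weaker one. From D0 to D10 the largest rise was at chromosome 11, 120670001 to 120680000, with 7600 ± 871 bp at D10 and no covered bp at D0 (SD, n = 3, limma adjusted p = 8.65e-06). Chromosome 15 gave a pair of the next windows, 8289 ± 1556 bp from 38.3 ± 66.4 at 76000001 and 6039 ± 1086 bp from none at 88990001. The remaining rises were at 179920001 on chromosome 2 and 53420001 on chromosome 19. In each of these 5 rises, 1 or 2 of the 3 whole D0 lists had a deposited peak. The largest falls from D0 to D10 were at 80410001 and 20770001 on chromosome 10, 90450001 on chromosome 8, 55540001 on chromosome 1 and 114390001 on chromosome 13, from 2457 to 2950 mean bp to none. Those at 20770001, 55540001 and 114390001 had no deposited peak at all in any D10 library.

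The lists were then set against embryonic stem cells, which are pluripotent. Of the strongest WT peaks, 3.58 ± 0.165% at D0, 6.35 ± 0.146% at D2 and 11.1 ± 0.252% at D10 overlapped one of 12931 peaks found in at least 2 of the 3 mESC lists (SD, n = 3 each). The days differed in a two-sided exact permutation test (F, p = 0.00357, the smallest possible). Each pairwise difference reached the smallest exact p of 0.1. The shift was steepest for the 72 hour mESC list, which held 2.09 ± 0.301% of the strongest peaks of D0, 3.75 ± 0.131% of D2 and 17.7 ± 0.543% of D10 (SD, n = 3 each). For the 12 hour list the shares were 7.76 ± 0.358%, 13.3 ± 0.203% and 21.2 ± 0.501%. The 0 hour list behaved otherwise, with 12.2 ± 1.29% at D0, 16.5 ± 0.377% at D2 and 10.3 ± 0.814% at D10 (SD, n = 3 each). All 3 lists gave the same exact permutation p of 0.00357 over the days, but the D10 minus D0 difference was 13.4 points for the 12 hour list, 15.6 for the 72 hour list and -1.86 for the 0 hour list.

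**Figure D2:**
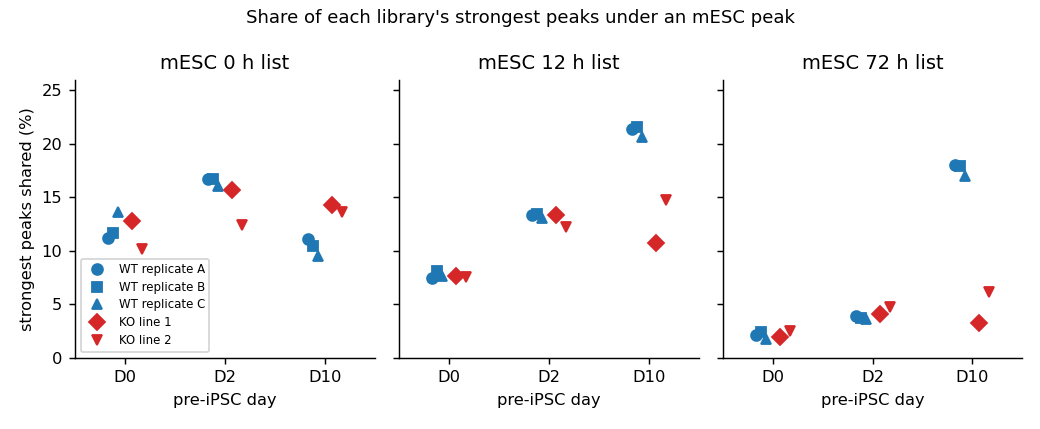
Percentage of each library's 55130 strongest peaks that overlap a peak of the 0, 12 or 72 hour mESC list by at least 1 bp, by day; each point is a library. At D10 the WT libraries share 17.0 to 18.01% of peaks with the 72 hour list, and KO1 and KO2 share 3.23% and 6.16%.

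The mESC lists of 0, 12 and 72 hours also differed from each other. They held 30791, 33576 and 24130 peaks over 9.67, 9.55 and 7.10 Mb at 0, 12 and 72 hours. The 0 and 12 hour lists overlapped by 10.4% of the bp in either, the 12 and 72 hour lists by 9.36%, and the 0 and 72 hour lists by 2.22%. Restricted to 24120 peaks each, the lists formed 62109 regions, of which 751 had a peak at all 3 times, 18721 at 0 hours alone, 15222 at 12 hours alone and 18867 at 72 hours alone. Of the peaks with a -log10 q of at least 5, the 3 lists held 21493, 14005 and 14313. With 1 library per time there was no replicate check.

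Chromosome 8 held 13.2% of the 12 hour and 11.9% of the 72 hour mESC peaks, against 6.95% at 0 hours and 5.27 to 6.32% of the strongest peaks in WT pre-iPSC libraries. Without chromosome 8 the D10 minus D0 difference in the share with the 72 hour list was 14.7 points.

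The effect of the knockout was asked day by day. KO and WT lists overlapped by 31.5% on average at D0 (6 pairs, 23.4 to 39.1%), where WT lists overlapped each other by 35.8%. At D2 the values were 35.4% (29.1 to 42.6%) and 47.5%, and at D10 they were 10.9% (6.07 to 15.4%) and 30.8%. KO1 and KO2 overlapped each other by 28.8%, 27.6% and 19.6% at D0, D2 and D10. Mean overlap with the WT lists of the same day differed between KO and WT by -4.32 points at D0 (two-sided exact permutation p = 0.6), -12.1 at D2 (exact p = 0.1) and -19.9 at D10 (exact p = 0.1, the smallest that 2 against 3 allow). KO1 at D10 overlapped WT lists of D0, D2 and D10 by 24.9%, 37.8% and 7.69% on average, and KO2 by 9.30%, 26.8% and 14.0%. Both KO D10 lists thus shared more with WT D2 lists than with WT D10 lists. Run names of a single style may mark a batch: of D10 lists within a style, KO1 and WT B overlapped by 7.94% and KO2 and WT C by 12.0%, and WT A had no KO list of its style.

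**Figure D3:**
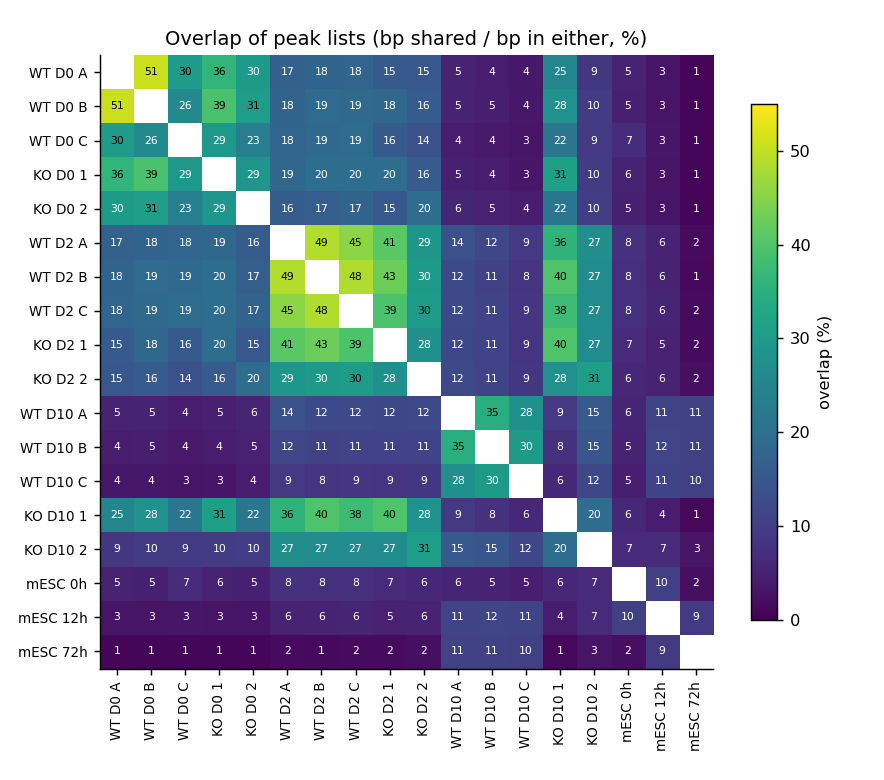
Overlap of every pair of peak lists, as bp shared in percent of bp in either, for the 55130 strongest peaks of each pre-iPSC library and the whole mESC lists. WT D10 lists overlap each other by 27.6 to 34.8%, and KO D10 lists by 6.07 to 15.4%, with a WT D10 list.

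The regions that WT cells gained from D2 to D10 seldom had a peak in KO cells at D10, and those that WT cells lost often had one. To avoid choosing regions on the same libraries that were then measured, gains and losses were called from a pair of WT letters and read in the remaining WT letter and in each KO line (13907 to 19454 gained and 52436 to 61934 lost regions). Of gained regions, 68.2 ± 13.2% had a D10 peak in the held-out WT library (SD, n = 3), against 3.03% in KO1 and 17.4% in KO2. At D2 these gained regions had a peak in 8.99 ± 8.25% (SD, n = 3), 11.2% and 9.56% of cases, so the share fell in KO1 and rose in KO2. Of lost regions, 8.22 ± 5.00% had a D10 peak in the held-out WT library (SD, n = 3), against 70.9% in KO1 and 50.2% in KO2. At D2 the same lost regions had a peak in 81.8 ± 11.1% (SD, n = 3), 79.4% and 57.6% of cases; regions with a KO peak on both days were not counted. Over D0 to D10, gained regions had a D10 peak in 72.0 ± 13.3% of WT, 17.9% of KO1 and 38.5% of KO2, and lost regions in 4.81 ± 3.09%, 64.3% and 30.7% (SD, n = 3). Permuting the 5 values gave a two-sided permutation p of 0.1, the smallest possible, for each of these 4 differences at D10. Regions were not called anew for each assignment, and KO libraries never served for calling. The values are thus not interchangeable, and this p is only a rough guide.

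The 9683 regions with a peak in all 3 WT libraries at D10 and in none at D0 or D2 had a peak in 1.51% of cases in KO1 at D10 (95% Wilson interval 1.28 to 1.77%) and 14.9% in KO2 (14.2 to 15.6%). In the 72 hour mESC list, 33.9% of them had a peak (33.0 to 34.9%), against 5.67% of all regions. The 12368 regions present at D0 and D2 and absent at D10 in WT had a D10 peak in 93.7% of cases in KO1 (93.3 to 94.1%) and 56.0% in KO2 (55.1 to 56.9%), but in 0.493% in the 72 hour mESC list. Both classes rest on whole lists, which differ in length between days. With the strongest peaks alone, 10661 regions were found at D10 alone, with a D10 peak in 1.53% (KO1) and 15.8% (KO2). Those present at D0 and D2 and absent at D10 then numbered 4822, with 93.1% and 49.9%. Intervals cover counting error over regions within a library only and miss the spread between libraries. The peaks also rest on amplified reads without molecular identifiers.

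**Figure D4:**
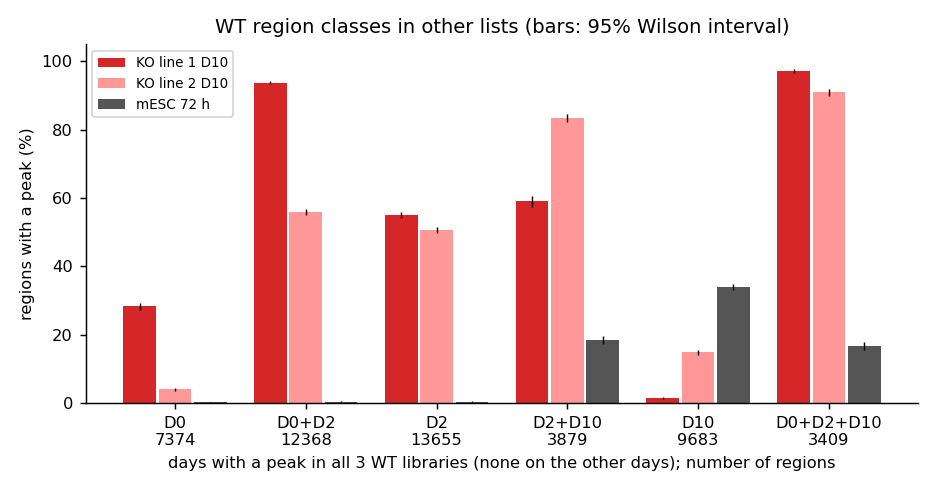
Percentage of WT regions that have a peak in KO1 at D10, KO2 at D10 and the 72 hour mESC list, by the days on which all 3 WT libraries had a peak (no WT library on the other days); error bars are 95% Wilson intervals and the number of regions stands under each class. Of the regions found in WT at D0 and D2, 93.7% and 56.0% have a KO peak at D10, and of those found in WT at D10 alone, 1.51% and 14.9%.

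In the limma fit of all 15 pre-iPSC libraries (15744 windows), KO and WT differed in 8 windows at D0 (6 higher and 2 lower in KO) and in 4 at D2 (all lower in KO). The balance at D0 turned to 27 higher and 90 lower with all deposited peaks scaled to a single total, to 250 and 318 with every window that had a covered bp, to 66 and 207 with KO2 as the only line, and to 3 and 6 without KO1 D0. The largest was at D0 on chromosome 4 (148300001 to 148310000), with 2331 ± 1244 bp in KO (SD, n = 2) and no covered bp in WT (limma adjusted p = 0.00893), though 2 of 3 WT libraries had a weaker peak. At D2 it was on chromosome 11 (79490001 to 79500000), with 2210 ± 360 bp in WT (SD, n = 3) and no covered bp in KO (limma adjusted p = 0.0382), though both KO libraries had a weaker peak. With KO2 as the only KO line, 273 windows differed at D0 and 507 at D2; with KO1 alone, 1 and 37. Leaving out single libraries gave 0 at D0 without KO2 D0, 4 without WT D0 A and 32 without WT D0 C. At D2 they gave 58 without KO1 D2, 2 without KO2 D2 and 0 without each of the 3 WT D2 libraries (limma, 773 to 825 at an unadjusted p under 0.05). The 0 at D0 came with 1130 at that unadjusted p.

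At D10, 3276 windows were higher and 797 lower in KO than in WT, and the median window was 0.66 higher (log2). Relative to that median, 1522 were higher and 1530 lower, and with every window that had a covered bp tested, 3778 were higher and 6206 lower. With all deposited peaks and no scaling, 9573 were higher and 362 lower. The largest excess in KO was at chromosome 11, 18770001 to 18780000, with 4059 ± 647 bp (SD, n = 2) and no covered bp in WT (limma adjusted p = 2.05e-05). Others were on chromosome 18 (56870001, 3784 ± 1028 bp), chromosome 13 (114390001 and 114400001, 3598 ± 667 and 3264 ± 755 bp) and chromosome 8 (126070001, 4771 ± 1023 bp against 98.9 ± 171 in WT). The windows on chromosomes 18 and 13 had no covered bp in WT, those on chromosomes 11 and 13 no deposited WT peak at all, and the first on chromosome 13 was also among the largest WT falls from D0 to D10. The largest deficits in KO, all with no bp under the strongest peaks there, were on chromosome 15 (75930001, 4975 ± 726 bp in WT), chromosome 12 (111850001, 4839 ± 558), chromosome 17 (84860001, 4631 ± 466) and chromosome 2 (76540001 and 76550001, 4408 ± 339 and 4345 ± 1142; SD, n = 3). In each of the 5, at least 1 KO D10 library had a weaker deposited peak. The chromosome 15 window holds the gained region at 75932829 to 75936548, and KO2 had a peak in it. The chromosome 12 and 17 windows were also among the largest WT rises from D2 to D10, a contrast that uses the same WT D10 libraries. The D10 count of 4073 was 1934 without the KO1 D10 library and 2514 with KO2 as the only line, and 3939 without chromosome 5. The deficits numbered 423, 320 and 348 without WT D10 A, B and C. With the run-name style as a block the count was 3924.

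Whether the change over days itself differed was tested by the interaction of arm and day. From D0 to D2 no window passed (limma, 888 at an unadjusted p under 0.05). In KO, windows that rose in WT over that interval had a median log2 change of 1.21 in KO1 and 1.07 in KO2, and those that fell had -1.26 and -0.83. Of the 2189 windows that rose, 85.6% and 76.7% were higher at D2 in KO1 and KO2. These windows were chosen on the WT libraries. In windows called to rise on a pair of WT letters (215, 251 and 2081 without A, B and C), the held-out WT libraries had medians of 2.64, 2.46 and 1.36, against 1.79, 1.64 and 1.21 in KO1 and 1.46, 1.502 and 0.98 in KO2. In those called to fall (17, 18 and 902) the medians were -2.48, -2.16 and -0.46 in WT, -1.73, -2.54 and -1.03 in KO1, and -1.31, -1.91 and -0.57 in KO2. From D0 to D10 the change differed in 1260 windows, 1006 more positive in KO and 254 more negative (336 and 409 relative to the median window, and 3977 and 75 with all deposited peaks and no scaling). With every window that had a covered bp tested the balance turned, to 975 more positive and 2167 more negative. The interaction count was 532 without KO2 D0, 712 without WT D0 A, 714 without KO1 D10, 766 without WT D10 C, 770 without WT D10 B, 781 without WT D0 B and 2155 without KO2 D10. The more negative windows alone numbered 115, 71 and 76 without WT D10 A, B and C. With KO1 as the only line the count was 1923, and with the KO line as a block 1939 (1507 and 432). Within KO, limma called 236 windows up and 47 down from D0 to D2, 135 up and 18 down from D0 to D10, and none from D2 to D10 (392 at an unadjusted p under 0.05). With the KO line as a block these were 374 up and 88 down, 348 up and 76 down, and again none (622 at that unadjusted p). Single libraries decided them: from D0 to D2 none passed without KO1 D2 (2245 at an unadjusted p under 0.05), 8 without KO2 D0 and 78 without KO2 D2. From D0 to D10 none passed without KO2 D0 or KO2 D10 (1822 and 1817 at that unadjusted p), 372 without KO1 D0 and 1252 without KO1 D10, where the balance turned to 556 up and 696 down. From D2 to D10, 57 passed without KO1 D10. In windows called from D2 to D10 on a pair of WT letters, the held-out WT letter had median log2 changes of 2.00 to 2.66 for rises and -2.49 to -2.11 for falls. KO1 had 0 for rises and 0.12 to 0.14 for falls, and KO2 had 0 and -0.21 to -0.20. A median of 0 arises from windows with no covered bp on either day, so it is not a measured lack of change. Of the called rises, 23.2 to 27.4% were higher at D10 in KO1 and 46.5 to 49.3% in KO2, against 93.1 to 97.7% in the held-out WT letter. In windows called the same way from D0 to D10, the held-out WT letter had 1.88 to 2.70 for rises and -2.40 to -1.85 for falls. There KO1 had 0 to 0.03 and -0.06 to -0.004, and KO2 had 1.18 to 1.28 and -0.62 to -0.44.

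At D10 the share of peaks in common with the 2-of-3 mESC set and with the 12 and 72 hour lists was lower in KO than in WT, but that with the 0 hour list was higher. Of the strongest peaks, the part in the 2-of-3 mESC set was 5.00% in KO1 and 6.97% in KO2, against 11.1 ± 0.252% in WT (SD, n = 3, difference -5.13 points, exact permutation p = 0.1, the smallest possible). For the 72 hour list it was 3.23% and 6.16% against 17.7 ± 0.543% (SD, n = 3, difference -13.0 points, exact permutation p = 0.1). At D0 the differences were -0.07 points (exact p = 0.8) and 0.16 points (exact p = 0.7). At D2 they were -0.395 points and, for the 72 hour list, 0.663 points, KO being higher there (exact p = 0.1 each). For the 12 hour list the D10 shares were 10.7% in KO1 and 14.8% in KO2 against 21.2 ± 0.501% in WT (SD, n = 3). For the 0 hour list they were 14.3% and 13.6% against 10.3 ± 0.814% (SD, n = 3). KO against WT was not tested for these lists.

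The lines of the KO arm also differed from each other on chromosome 5. It held 10.3%, 12.8% and 11.7% of the strongest peaks of KO1 at D0, D2 and D10, against 5.41%, 5.00% and 4.67% in KO2 and 5.47 to 6.72% in the 9 WT libraries. KO1 was above all 3 WT libraries on all 3 days in 15 of the 16 bins of 10 Mb along chromosome 5, and in 2 of 259 bins elsewhere. Without chromosome 5 the overlap of KO with WT D10 lists still differed by -19.9 points.

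**Figure D5:**
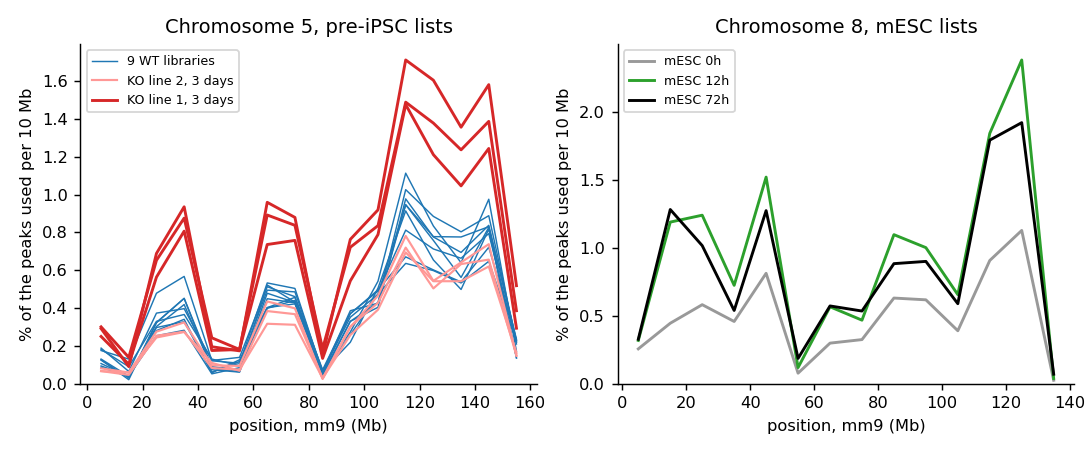
Percentage of the peaks used in each list (55130 strongest for pre-iPSCs, whole lists for mESC) that fall in each 10 Mb bin of chromosome 5 (pre-iPSC lists) and chromosome 8 (mESC lists), by position on mm9. KO1 lies above the WT libraries of the same day in 15 of 16 bins of chromosome 5, and the 12 and 72 hour mESC lists above the 0 hour list in all 14 bins of chromosome 8.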

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

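The tests of depth, of a wrong label for each KO D10 library and of regions that give a peak in any library were chosen only after the result was seen, as were the unpaired test of peak number, the comparison without chromosome 8 and the overlap of D10 lists itself.

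The change from D0 to D10 differed between KO and WT in 1260 windows, and KO D10 lists overlapped WT D10 lists by at most 15.4%. Depth as the whole cause is argued against by the pair of WT D10 lists farthest apart in depth (B and C), which overlapped by 29.98%. A batch marked by run-name style is argued against by same-style pairs, which overlapped by 7.94% (KO1 and WT B) and 12.0% (KO2 and WT C), below the lowest WT pair of 27.6%. D2 libraries with a wrong label are argued against by mean overlaps with WT D0 lists of 24.9% (KO1 at D10) and 9.30% (KO2 at D10), outside the 14.9 to 18.8% of the 5 D2 libraries. No biological explanation was tested, so a difference between the arms, differences between the lines and a mixture of cells stay open, and the labels do not say that both lines lack the same gene.

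WT D10 lists shared 17.7 ± 0.543% of their strongest peaks with the 72 hour mESC list (SD, n = 3), 15.6 points above D0. Regions that give a peak in any library are argued against, since 33.9% of the regions found at D10 alone had a 72 hour peak against 5.67% of all regions. The strongest 10% of each WT D10 list was shared in 32.4 to 34.1% of cases, against 9.20 to 11.3% of the weakest 10% (lowest difference 22.3 points). In every pre-iPSC list the strongest 10% was shared more often than the weakest, so this gap alone decides nothing about weak peaks. The strongest 10% of the WT D0 lists was shared in 2.05 to 3.87% of cases, so weak peaks near the threshold as the whole cause are argued against. The chromosome 8 excess is argued against by a difference of 14.7 points without that chromosome. The 0 hour list went the other way, from 12.2% at D0 to 10.3% at D10 (-1.86 points), so the values show no approach to mESC in general, and no biological explanation was tested. A direct effect of the medium stays open too, since no WT cells kept to D10 without it were compared. KO cells of the same treatment label shared 3.23% and 6.16%. With 1 mESC library per time, differences between mESC libraries unrelated to time stay open as well.

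Chromosome 5 in KO1 and chromosome 8 in the 12 and 72 hour mESC lists held more peaks than in the other libraries. Extra copies of most of the chromosome may explain both, as KO1 lay above all 3 WT libraries on all 3 days in 93.8% of the 10 Mb bins of chromosome 5 (0.772% of bins elsewhere), and both later mESC lists above the 0 hour list in 100% of the bins of chromosome 8 (24.1% elsewhere). A few dense clusters of peaks on chromosome 5 are argued against, since the 2 bins with the largest excess held 24.3% of it. Gain of chromosome 8 is a known change of mouse embryonic stem cells in culture, but no copy number was measured here, so this remains a hypothesis. If it holds, the 0 hour mESC library may differ from the later ones by more than time, which was not tested. No biological explanation by group was tested, as the other KO line did not show the excess.

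The log2 change of peak number from D0 to D10 differed by 0.90 between the arms; read by letter and line, it lay below 0 in all 3 WT letters and above 0 in both KO lines. Window values showed no pairing of samples by WT letter, but they rest on lists of a single length and cannot tell for peak number. Without pairing the difference did not pass (two-sided exact permutation within days, 100 assignments, p = 0.08). With changes taken within letter or line the exact permutation p was 0.1, the smallest that 2 against 3 allow. Within a run-name style, the change was 0.88 in KO1 against -0.58 in WT B, and 0.36 in KO2 against -0.17 in WT C. WT D0 C held 43 peaks on chromosome Y and 9 on the mitochondrial genome, data outside the comparisons, where the other libraries held 0 to 10 and 0 to 1; its background was its own rather than the shared input.

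Other splits of the libraries were counted for the results of tests over many regions or windows. Of the 10 splits of 6 WT libraries, only 1, the real one, gave as many regions gained or lost: 32574 from D0 to D2 (highest other 2630), 51222 from D2 to D10 (2186) and 45657 from D0 to D10 (1979). The same held for windows in limma, again in 1 split of 10: 2629 (highest other 1), 6951 (0) and 7356 (0). With 10 splits no share can fall under 0.05. For the 3 days together, 1 of 100 splits of the 9 libraries, the real one, gave as many windows (8888, highest other 5174). Only a part of the possible splits was run, so chance is unlikely there but not excluded. The splits speak only for these libraries, whose replicates may be technical.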

How the results depend on the processing

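The windows of 5 and 20 kb, median-centring, the style block, the runs without chromosome 5 or 8, mESC lists of a single length, the held-out regions, the overlap of D10 lists, the 72 hour mESC share, the contrasts within KO and the KO line block were chosen after the data were seen. Over 291 alternatives for 27 results, 194 were counted as kept, 94 as moved by more than the spread or 1.5 times, 2 as stronger and 1 as reversed. Counts of windows were judged by their total alone and not by direction, so turned balances stand among the kept or the moved. An example counted as kept is D10 against D0 without WT D0 A (3240 up and 2728 down, main 3356 and 4000). Causes were not tested unless stated. Of the 194, 6 are void: a 50% overlap cannot change which merged regions have a peak. Counts are windows in the order D2 against D0, D10 against D2, D10 against D0 in WT, then KO against WT at D0, D2 and D10, then interactions.

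With all deposited peaks scaled to a single total (more windows tested), D10 against D2 gave 11614 and D10 against D0 13903 windows, KO at D0, D2 and D10 117, 0 and 8243, and the D0 to D10 interaction 3031. Without scaling the WT counts were 4805, 15042 and 11743, the KO counts 0, 0 and 9935, and the interaction 4052. A pseudocount of 50 bp gave 1724 for D2 against D0, 87 and 12 for KO at D0 and D2, and 9 for the D0 to D2 interaction; 1000 bp gave 1 for KO at D0. Testing any window with a covered bp gave 9267, 16379 and 22087 in WT, 568, 0 and 9984 in KO, and 3142 for the interaction, and turned the balance of D2 against D0 (3643 up, 5624 down) and of the interaction (975 and 2167). A mean of at least 2000 covered bp left few windows and gave 147, 107 and 151, then 0, 0 and 126, and 26. KO at D0 and D2 gave 27 and 0 with 5 kb windows, 1 and 0 with 20 kb, and 4 and 0 with the style block, which left 3924 at D10 and 1134 for the interaction. Median-centring gave 745 for the interaction. Beside totals, single directions moved by over 1.5 times. Falls from D0 to D2 numbered 253 and 720 with 50 and 1000 bp, 277 and 739 with 5 and 20 kb, 292 in the fit of all 15 libraries and 1 at a mean of 2000 bp. Rises from D2 to D10 numbered 1304 with 5 kb and 1094 in the fit of all 15. D10 against D0 turned to 113 up and 38 down at 2000 bp. KO deficits at D10 numbered 514 with 50 bp and 437 with 5 kb, and the interaction split 537 to 390 with 1000 bp and 645 to 247 with 20 kb. KO at D0 turned to 27 up and 90 down with all peaks scaled. KO2 as the only line gave 273, 507 and 2514 for KO by day, and KO1 alone 1, 37 and 5434, with 1923 for the interaction.

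With the strongest peaks alone, regions gained and lost numbered 9005 and 8725 (D0 to D2), 11144 and 15306 (D2 to D10), and 15151 and 17494 (D0 to D10); peaks with a -log10 q of at least 5 gave 5896 gained from D2 to D10 and 11800 from D0 to D10. At that q the 12 and 72 hour mESC lists held 14005 and 14313 peaks. The share with mESC reversed for the 0 hour list alone (exact permutation p = 0.00357, D10 minus D0 -1.86 points). The 72 hour share differed by 14.7 points without chromosome 8 and by 21.1 with lists of the 72 hour list's length.

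WT letters did not pair the samples in window values. These rest on lists of a single length, so they cannot tell for peak number. With the replicate block the WT peak number passed the threshold (exact permutation p = 0.0278, the smallest it can give), deviations of a letter correlated between days by -0.03 to 0.05, not every WT library correlated best with its own letter, and window counts were 2276, 6787 and 7184 in WT, 8, 4 and 4089 in KO and 0 and 1498 for the interactions; it changed no other call. KO lines were taken to pair the KO samples. The correlation of a line between days includes chromosome 5, where KO1 was in excess, and line goes with run-name style, so these were not told apart. With the KO line block alone the D0 to D10 interaction was 1939, and windows within KO 462 (D0 to D2), 0 (D2 to D10, limma, 622 at an unadjusted p under 0.05) and 424 (D0 to D10). Leaving out each library in turn (a lone library is assumed to vary like the other groups) gave exact permutation p of 0.0286 to 0.218 for WT peak number (0.0286 without WT D0 C), 0.36 to 0.925 for KO against WT, and 0.00357 throughout for the mESC share. That p for the mESC share is the smallest its test can give, so it does not measure how far the share moved. The D10 overlap difference ran from -23.1 to -16.7 points. Regions ran from 26678 to 42414 gained and 8156 to 25400 lost (D0 to D2), 10297 to 18870 and 42867 to 59826 (D2 to D10), and 19644 to 34023 and 27011 to 56361 (D0 to D10). The largest counts of gains came without WT D2 C (42414) and WT D10 C (18870 and 34023), and of losses without WT D0 C (25400 and 56361). The 72 hour share differed by 15.4 to 15.9 points. Windows ran from 1440 (without WT D2 A) to 3443 for D2 against D0 (1521 without WT D2 B, 1620 without WT D2 C, 1748 without WT D0 A), 5301 to 6674 for D10 against D2 and 5794 to 8007 for D10 against D0. KO against WT ran from 0 (without KO2 D0) to 32 (without WT D0 C; 4 without WT D0 A) at D0, from 0 (without each WT D2 library) to 58 (without KO1 D2; 2 without KO2 D2) at D2, and from 1934 (without KO1 D10) to 4565 at D10. The D0 to D10 interaction ran from 532 (without KO2 D0) to 2155 (without KO2 D10), with 712 and 781 without WT D0 A and B, 770 and 766 without WT D10 B and C, and 714 without KO1 D10. Within KO, counts ran from 0 (without KO1 D2) to 354 for D2 against D0, 0 to 57 (without KO1 D10) for D10 against D2, and 0 (without KO2 D0 or KO2 D10) to 1252 (without KO1 D10; 556 up and 696 down) for D10 against D0, the counts of 0 with 770 to 2245 at an unadjusted p under 0.05. The D0 to D2 interaction was 0 in limma under all alternatives run but the 50 bp pseudocount (28 to 4597 windows at an unadjusted p under 0.05), and the counts of 0 for KO at D0 or D2 came with 12 to 6505. Promoter regions, gene lists and the distribution over genes were not run for want of an mm9 annotation. In simulated data for WT D10 against D0, no window changed by log2 1 was called, so changes of that size could be missed; what depth or groups of 2 add was not tested.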

Other observations

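The tests of chromosome shares and the values by region class were chosen only after the data were seen. The share of the strongest peaks differed between the WT days on 16 of the 20 chromosomes. Chromosome 4 held 6.06 ± 0.117%, 6.59 ± 0.125% and 6.98 ± 0.0219% of peaks at D0, D2 and D10, and chromosome 8 held 5.30 ± 0.0329%, 5.66 ± 0.0800% and 6.16 ± 0.141% (SD, n = 3 each). On chromosomes 10 and 15 the means were 5.76, 6.04 and 6.31%, and 4.00, 4.28 and 4.64%. On each of these 4 chromosomes all 3 D10 libraries lay above all 3 D2 libraries, and these above all 3 D0 libraries (two-sided exact permutation F over 20 chromosomes, adjusted p = 0.0102 each). Chromosomes 17 and 19 had lower means at D0 than later, with 4.77, 5.46 and 5.45%, and 2.98, 3.23 and 3.29%. Chromosome 1 had 7.04, 6.22 and 6.12%, and chromosome 2 had 7.86, 8.04 and 7.31%. On chromosomes 9, 13, 14 and 18 the mean was highest at D0 and lowest at D2, with 5.54, 5.12 and 5.26%, 5.26, 4.50 and 4.66%, 3.97, 3.41 and 3.73%, and 3.54, 3.02 and 3.27%. On chromosomes 12 and 16 it was lowest at D2 and highest at D10, with 4.43, 4.05 and 4.49%, and 3.42, 3.12 and 3.46%. Adjusted p of these 10 chromosomes ran from 0.0102 to 0.0446 (exact permutation), and chromosomes 3, 5, 6 and 7 did not pass 0.05. Chromosome 11 had its highest mean at D2, with 6.99 ± 0.0762%, 8.21 ± 0.333% and 7.15 ± 0.0115% (SD, n = 3, exact permutation adjusted p = 0.0102). Chromosome X, with 6.32% of the span, held 0.602 ± 0.195%, 0.216 ± 0.0136% and 0.258 ± 0.0659% (SD, n = 3, exact permutation adjusted p = 0.0255). At D10 the KO1 and KO2 shares of chromosome 8 were 5.21% and 5.75%; the chromosome 5 excess of KO1 lowers its other shares.

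The transient regions, 13655 with a peak in all 3 WT libraries at D2 and in none at D0 or D10, had a D2 peak in 77.4% of cases in KO1 and 47.2% in KO2. They had a D10 peak in 55.1% (95% Wilson interval 54.2 to 55.9%) and 50.6% (49.7 to 51.4%). In mESC they had a peak in 10.0% of cases at 0 hours, 5.06% at 12 hours and 0.403% at 72 hours. Their number depends on list length, since WT D2 lists were the longest on average. With the strongest peaks alone, 4570 such regions were found, with a D10 peak in 54.6% (KO1) and 48.9% (KO2). The 3879 regions present in WT at D2 and D10 and absent at D0 had a D10 peak in 59.1% of cases in KO1 and 83.4% in KO2, and a peak in 36.2% in the 12 hour mESC list. The lines parted on the 7374 regions present in WT at D0 alone: KO1 at D10 had a peak in 28.4% of them (27.4 to 29.5%) and KO2 in 4.095% (3.67 to 4.57%), a difference between a pair of libraries with no replicate. Only 24 regions were present in WT at D0 and D10 and absent at D2.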
